A study of Mus musculus with 8 samples.

How the data were processed

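RNA from whole liver was measured on GeneChip arrays in 8 mice aged 6 weeks, 3 controls and 5 POMCMfn2KO mice, in which the mitochondrial fusion gene Mfn2 was deleted in the POMC neurons of the hypothalamus. Per the labels, the mice had chow and water freely available, and lived under 12 h of light and 12 h of dark; RNA was isolated with Trizol and a column kit and made into biotin-labelled cRNA. The labels give no sex, collection time, date or batch, and name the arrays of each group as biological replicates. The deposited values are log2 expression levels per probe set, made by the authors with RMA from the affy package (versions not given); the scanner files were not used here. The median over all probe sets lay between 5.79 and 5.81 in every array, and no value was transformed again. Array values carry no read depth, so the number of arrays limits the precision.

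Of the 45101 probe sets, 64 were controls, 34945 had exactly 1 gene symbol, 932 had several and 9160 had none. For each of the 18193 genes with a named probe set, the probe set with the highest mean over the 8 arrays was kept. Genes whose probe set had a mean below 5.80, the median of the non-control probe sets, were left out as dim, which left 11986 genes for the test and 6207 untested. Some probe sets can bind transcripts of related genes, so values of Ang, Saa1, Saa2, Orm2, Mt1, Mt2, Gstm3, Ugt2b38 and Cyp4a14 can include those of close relatives.

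Genes were tested with limma 3.58.1 in R 4.3.3 (a linear model per gene with moderated variance, no trend, not robust), POMCMfn2KO minus control, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes said to rise, fall or change passed that threshold. The list test was camera from limma with a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over 39 lists; camera was repeated with a correlation estimated for each list, and fry, which tests whether the members of a list move on balance in 1 direction, was run beside it. The mean of each list was also compared by an exact permutation test, 2-sided, over the 56 splits of the 8 arrays, where the smallest possible p is 0.0179. On simulated data of the same size, the gene test recovered 71% of 100 genes with a log2 change of 0.5 and 97% of 100 with a log2 change of 1, with 11 false calls. The simulated genes were independent and had the same spread in both groups. The real groups differ in spread, so these figures do not measure the performance on the real arrays.

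The design, the tests, the alternatives and 41 gene lists were fixed before the data were examined. The lists were gluconeogenic enzymes, regulators of gluconeogenesis, glycolysis, glycogen metabolism, insulin signalling, lipogenesis, cholesterol synthesis, fatty acid oxidation and PPARa targets, lipid droplets and lipoproteins, bile acids, the unfolded protein response, the integrated stress response, NRF2 targets, the acute phase response, the interferon response, glucocorticoid-responsive genes, immediate early genes, the circadian clock, oxidative phosphorylation, mitochondrial dynamics, xenobiotic metabolism, urea cycle and amino acid catabolism, secreted proteins, male-biased genes, female-biased genes, sex chromosome genes, proliferation, fetal and young liver genes, the melanocortin axis with Mfn2, and markers of 12 cell types. Of their 774 entries, 693 matched a gene with a named probe set.

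Named genes followed a rule fixed at the same time: the 12 genes that rose and the 12 that fell with the largest log2 change, the 4 members with the lowest p of each list described at length, and 18 genes chosen for the study's question, of which 2 had no named probe set and were not analysed here. The choice of 23 lists to describe at length was made with the results known: lists that passed camera, lists with at least 4 members past the gene test, and the gluconeogenic enzymes. Other members of lists that are named were chosen after their values were seen.

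The alternatives changed the filter, the choice of probe set, the scaling, the variance model, the threshold and the use of replicate numbers as a block, and left out each array in turn. Added after seeing the data were array weights by genotype, the 3 controls averaged to 1 sample, and a fit without POMCMfn2KO arrays 2 and 3, which were high in pancreatic transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.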

Results

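Whole-liver gene expression was measured in 3 control and 5 POMCMfn2KO mice, 1 array per mouse. The single comparison, POMCMfn2KO against control liver, asks which hepatic genes differ when Mfn2 is lost from POMC neurons; the title of the series concerns hepatic glucose production. All values below are log2 levels, given as mean ± SD with n = 3 controls and n = 5 POMCMfn2KO, and changes are log2 differences.

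By the brightest probe set of each gene, the largest falls in POMCMfn2KO liver were those of Lcn2 and Saa2, and the largest rise was that of Ang. Lcn2, an iron-siderophore-binding acute phase protein, fell from 12.41 ± 0.14 to 7.27 ± 0.97, a 35.4-fold drop, and Saa2 fell from 13.35 ± 0.05 to 8.62 ± 0.21, 26.4-fold. Ang, a secreted ribonuclease, rose from 9.48 ± 0.08 to 13.45 ± 0.29, 15.7-fold, on its brightest probe set. Other bright probe sets of Ang gave log2 changes of 2.33 and 0.44, so its rank rests on the brightest one. Igfbp2, an insulin-like growth factor-binding protein, rose from 10.92 ± 0.05 to 13.42 ± 0.30. The other genes with the largest rises were Ugt2b38 (3.21), Tff3 (3.17), Hspa1b (2.18), Igfbp1 (2.11), Egfr (2.08), Serpina4-ps1 (2.00), Ccn2 (1.84), Creld2 (1.77), Hsph1 (1.72) and Tmem87a (1.67). Those with the largest falls were Saa1 (-3.66), Lgals1 (-3.60), Serpina7 (-3.34), Mt2 (-3.14), Mogat1 (-3.00), Orm2 (-2.88), Wfdc2 (-2.70), Mt1 (-2.61), Nat8 (-2.60) and Plin4 (-2.49). Other probe sets above the filter gave 0.04 and 0.08 for Egfr, with a further 3 at 1.18 to 1.77, and -0.51 for Mt1. Serpina7 (5.02 ± 1.36) and Mogat1 (5.37 ± 0.30) lay below the level used to leave out dim genes in POMCMfn2KO, so background limits the size and rank of their falls.

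Of 11986 genes tested with limma, 842 rose and 1310 fell, 2152 in all, with a median change of 1.33-fold among them; 52 rose and 109 fell by at least 2-fold. The excess of falls depended on the scaling: with each array centred on its median, 1055 rose and 1119 fell. Predicted genes and RIKEN clones made up 65 of the called genes, 22 up and 43 down. In 3417 genes (28.5%) the values of the groups did not overlap, against 3.57% by chance. The number of called genes was 821, 820 and 863 without control 1, 2 and 3, 1399 without POMCMfn2KO 3, and 640 without POMCMfn2KO 2 and 3, the arrays high in pancreatic transcripts. Ccn2, Mt1, Mt2 and Nat8 lost their calls without any single control, with adjusted p up to 0.0953, 0.0772, 0.0823 and 0.128; Ccn2 was also lost without POMCMfn2KO 2 or 3, and Nat8 without POMCMfn2KO 1, 2, 3 or 5. With a trended and robust variance, Mt2 (adjusted p = 0.0539) and Nat8 (0.0834) were lost, and without POMCMfn2KO 2 and 3 together all 4 were lost (Ccn2 0.120, Mt1 0.105, Mt2 0.0846, Nat8 0.176).

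Among the gluconeogenic enzymes, the phosphoenolpyruvate carboxykinase genes and the gene of the last step, glucose-6-phosphatase, were higher in POMCMfn2KO liver. G6pc, the catalytic subunit of glucose-6-phosphatase, rose from 12.52 ± 0.02 to 13.12 ± 0.24 (1.52-fold, adjusted p = 0.0128). Pck1, the cytosolic phosphoenolpyruvate carboxykinase, rose from 13.61 ± 0.07 to 13.96 ± 0.10 (1.28-fold, adjusted p = 0.0129), and its mitochondrial relative Pck2 rose from 6.46 ± 0.06 to 6.83 ± 0.08 (1.29-fold, adjusted p = 0.00734). Another probe set of Pck1 above the filter gave 0.62. Fbp1 (-0.15) and Pcx (-0.08) did not pass, and neither did the glycerol channel Aqp9 (-0.35, adjusted p = 0.0509). Of the 15 tested members, 3 rose and none fell; adjusted over the list alone, 3 rose and 1, Aqp9, fell. As a list the enzymes did not pass: the mean differed by 0.09 (exact permutation p = 0.339), the median was 0.05 and camera gave adjusted p = 0.361. G6pc lost its call without control 1, 2 or 3 (adjusted p up to 0.0598), Pck1 without control 1 or 3 (up to 0.0662) and without POMCMfn2KO 2 and 3 (0.0668); 1 member rose without control 1 or 3, and 2 fell without POMCMfn2KO 1 and 1 without POMCMfn2KO 4.

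**Figure D1:**
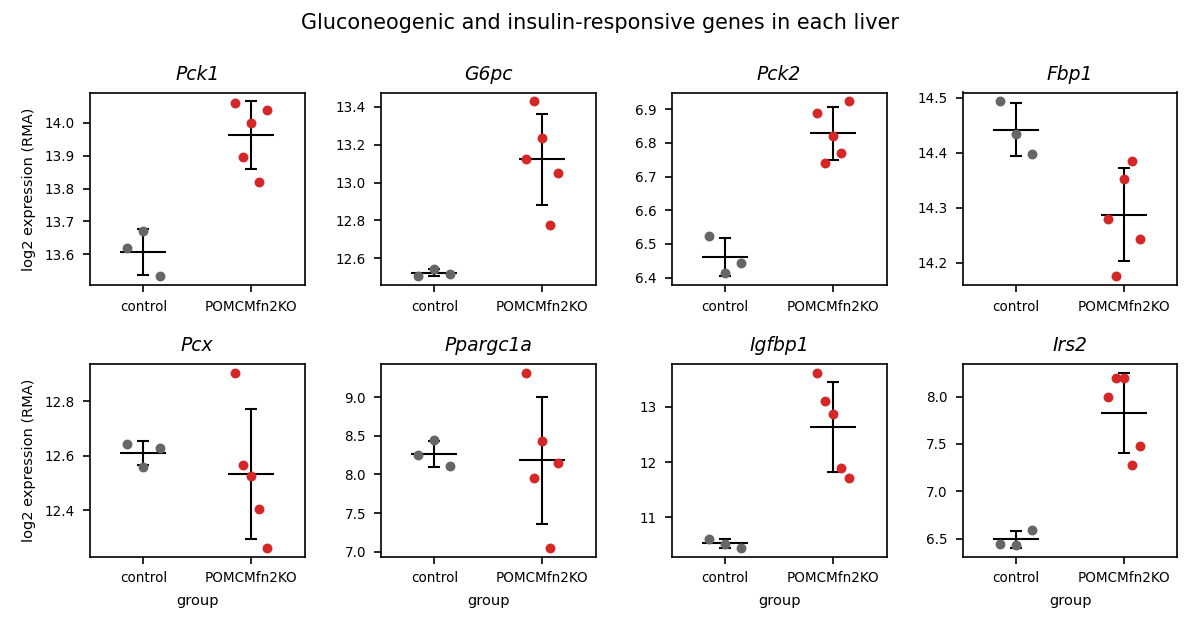
Log2 levels of gluconeogenic and related genes in each liver, 3 controls and 5 POMCMfn2KO; points are arrays and bars show the mean and SD of each group. G6pc, Pck1 and Pck2 rose, while Fbp1 and Pcx did not pass the gene test.

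Regulators of gluconeogenesis and genes of insulin signalling changed in both directions. Igfbp1, whose transcription insulin represses, rose from 10.52 ± 0.08 to 12.64 ± 0.82 (4.33-fold), and Irs2, an insulin receptor substrate, rose from 6.49 ± 0.09 to 7.83 ± 0.42 (2.52-fold). The transcription factor gene Creb1 rose (0.68) and the nuclear receptor gene Nr4a1 fell (-0.66); Ppargc1a (-0.09) and Foxo1 (-0.35, adjusted p = 0.209) did not pass. Among 19 regulators, 4 rose and 3 fell over all genes and adjusted over the list alone (camera adjusted p = 0.387). Of 24 insulin signalling genes, 6 rose and 3 fell; adjusted over the list alone, 8 rose and 3 fell (camera adjusted p = 0.0933). In that list Igfbp2 rose, while Socs3 (-0.80), an inhibitor of cytokine signalling, and Pdk1 (-1.27), here the gene of a pyruvate dehydrogenase kinase, fell; other probe sets of Socs3 gave -0.21 and -0.87. The number of regulators that fell was 1 without control 1, 2 or 3 or POMCMfn2KO 3, and the number of insulin signalling genes that fell was 5 without POMCMfn2KO 1. Without POMCMfn2KO 2 and 3, 2 regulators and 2 insulin signalling genes rose, and Igfbp1 lost its call (adjusted p = 0.0616).

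Genes of glycogen synthesis and breakdown and of glycolysis fell where they changed. Gbe1, the branching enzyme, fell by 0.67, Gyg, which primes glycogen, by 0.44, Phka2, a phosphorylase kinase subunit, by 0.43 and Ugp2, which makes UDP-glucose, by 0.41. Other probe sets of Ugp2 gave -0.46 to -0.72. In all, 4 of 15 glycogen genes fell and none rose, over all genes and adjusted over the list alone (camera adjusted p = 0.137; mean difference -0.20, exact permutation p = 0.0179). Of 9 glycolysis genes, the liver pyruvate kinase gene Pklr (-0.83) and the glucose transporter gene Slc2a2 (-0.58) fell and none rose, with 2 also adjusted over the list alone (camera adjusted p = 0.378). The glycogen count was 1 without control 1 or 3, 2 without control 2, 7 without POMCMfn2KO 4 and 1 without POMCMfn2KO 2 and 3, and the glycolysis count was 1 without any control or POMCMfn2KO 2 or 5, with 1 gene up without POMCMfn2KO 4. Gyg was lost without control 1 or 3 (adjusted p up to 0.060), Ugp2 without any control (0.0832) and Gbe1 without any control or POMCMfn2KO 2 (0.0931), and another probe set of Phka2 gave 0.01, its call being lost with the mean of all probe sets (0.113).

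Several genes that make and store fat fell in POMCMfn2KO liver. Srebf1, the gene of the lipogenic transcription factor SREBP1, fell from 10.56 ± 0.15 to 9.05 ± 0.21 (2.86-fold), and its lipogenic companions Thrsp (-2.03), Pparg (-1.05) and Acly (-0.56) fell, whereas Fasn did not pass (-0.05); other probe sets of Thrsp gave -1.61 and -0.04. Of 22 lipogenesis genes, 7 fell and 1, the elongase Elovl6 (0.37), rose; adjusted over the list alone, 8 fell and 1 rose. Camera gave adjusted p = 0.0445, and adjusted p = 0.406 with an estimated correlation. Among 20 lipid droplet and lipoprotein genes, 4 fell and none rose, over all genes and adjusted over the list alone (camera adjusted p = 0.137): Mogat1, an acyltransferase that fell from 8.37 ± 0.14 to 5.37 ± 0.30, Plin4, Cidea (-1.58) and Pltp (-1.42). Another probe set of Pltp gave -0.86. Mogat1 and Cidea (5.79 ± 0.12) lay below the level used to leave out dim genes in POMCMfn2KO, so background limits the size of these falls. Of 19 cholesterol synthesis genes, Nsdhl (-0.88), Fdps (-0.82) and Hmgcs1 (-0.51) fell and none rose, with 3 also adjusted over the list alone (camera adjusted p = 0.285). The lipogenesis list lost its call without control 1 or POMCMfn2KO 1, 2, 3 or 5 (adjusted p up to 0.0616), without POMCMfn2KO 2 and 3 together (0.0547), with array weights (0.0508), after quantile normalization (0.0557) and with the mean of all probe sets (0.0559); 4 of its genes fell without any single control, Elovl6 was lost without each control, and 3 rose without POMCMfn2KO 1. Of the lipid droplet genes, 2 rose without POMCMfn2KO 1 and 1 without POMCMfn2KO 4. Without control 1, 2 or 3 no cholesterol synthesis gene passed, and 1 passed without POMCMfn2KO 2.

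Among targets of PPARa, the fasting-activated receptor of fatty acid oxidation, more genes rose than fell. Fgf21, a hepatic hormone of fasting, rose by 1.29 (2.44-fold), Ehhadh, a peroxisomal oxidation enzyme, rose from 12.65 ± 0.01 to 13.91 ± 0.24 (2.40-fold), and Angptl4 rose by 0.78. The fatty acid transporter gene Cd36 fell from 11.48 ± 0.04 to 9.05 ± 0.26. Of 22 members, 8 rose and 1 fell, over all genes and adjusted over the list alone. Camera gave adjusted p = 0.00309, and adjusted p = 0.406 with an estimated correlation; 5 rose and 2 fell without POMCMfn2KO 2 and 3, and 2 fell without POMCMfn2KO 2. In bile acid synthesis and transport, 4 of 20 genes rose and none fell: Slco1a1 (1.32), Cyp7b1 (0.78), Cyp27a1 (0.66) and Abcb4 (0.35). Adjusted over the list alone, 4 rose and 2 fell (camera adjusted p = 0.306), and Cyp7a1, the rate-limiting enzyme of the classic pathway, did not pass (-0.72, adjusted p = 0.397). The bile acid count was 2 without any single control; Abcb4 (adjusted p up to 0.0892) and Cyp7b1 (up to 0.0985) were lost without any control, Cyp7b1 also without POMCMfn2KO 2, Abcb4 with replicate numbers as a block (0.0739), and 2 genes fell without POMCMfn2KO 4.

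Many chaperones and transducers of the unfolded protein response rose in POMCMfn2KO liver. Hspa5, the chaperone BiP of the endoplasmic reticulum, rose from 12.92 ± 0.05 to 13.79 ± 0.21 (1.83-fold), Creld2 rose from 9.04 ± 0.04 to 10.80 ± 0.53 (3.41-fold), and Manf (1.39), Dnajb9 (0.89) and Herpud1 (0.60) rose as well; other probe sets of Hspa5 gave 1.09 and 0.10. Ddit3, the gene of the factor CHOP, rose by 0.36 (adjusted p = 0.0270). Of 24 members, 12 rose and none fell; adjusted over the list alone, 16 rose. Camera gave adjusted p = 2.27e-09, and adjusted p = 0.406 with an estimated correlation. The pancreatic acinar markers were high in POMCMfn2KO 2 and 3, and without these arrays 6 members rose; 6 rose without control 3, and Ddit3 was lost without any control or POMCMfn2KO 2 (adjusted p up to 0.108) and with replicate numbers as a block (0.0661). In the integrated stress response list of 14 genes, Fgf21 and Ddit3 rose and the lipoprotein receptor gene Vldlr (-1.13) fell; adjusted over the list alone, 3 rose and 1 fell (camera adjusted p = 0.8995). In that list 1 gene rose without any control or POMCMfn2KO 2, none fell without control 1 or 2, 2 fell without POMCMfn2KO 1 and 3 without POMCMfn2KO 4.

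Many acute phase genes fell in POMCMfn2KO liver. Besides Lcn2 and Saa2, Saa1 fell from 14.46 ± 0.07 to 10.80 ± 0.29 (12.7-fold), Orm2 fell from 10.75 ± 0.05 to 7.87 ± 0.27 (7.34-fold), and Apcs, serum amyloid P component, fell from 13.39 ± 0.08 to 11.92 ± 0.17 (2.78-fold). Of 22 members, 12 fell and none rose; adjusted over the list alone, 17 fell. Camera gave adjusted p = 3.60e-09, and adjusted p = 0.406 with an estimated correlation; 1 member rose without POMCMfn2KO 4. Among 22 interferon response genes, 4 fell and none rose: Ifit1 (-0.96), Oasl1 (-0.78), the immunoproteasome gene Psmb8 (-0.70) and Irf1 (-0.38). Adjusted over the list alone, 5 fell; camera gave adjusted p = 0.0465, and adjusted p = 0.691 with an estimated correlation. The interferon call was lost without control 1 or 3 or POMCMfn2KO 1 or 4 (adjusted p up to 0.274) and with array weights (0.295), 2 members fell without any single control, and 3 rose without POMCMfn2KO 1. Oasl1 (adjusted p up to 0.0620) and Ifit1 (up to 0.103) were lost without any control, Ifit1 also without POMCMfn2KO 2 or 5.

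NRF2 targets of the antioxidant response fell where they changed, and glucocorticoid-responsive genes went both ways. Gstm3, a glutathione transferase, fell from 10.55 ± 0.12 to 8.32 ± 0.59 (4.68-fold; -0.71 on another probe set), with Gsta2 (-0.89), Nqo1 (-0.64) and Gpx4 (-0.37): 4 of 16 NRF2 targets fell and none rose, over all genes and adjusted over the list alone (camera adjusted p = 0.0954). Of 18 glucocorticoid-responsive genes, Igfbp1, Angptl4, Pck1 and Fkbp5 (1.26) rose, and Lcn2 and the metallothioneins Mt1 and Mt2 fell; adjusted over the list alone, 6 rose and 3 fell (camera adjusted p = 0.341, with a median of 0.10 and a mean of -0.28). Of 12 immediate early genes, Nr4a1, Fos (-0.61) and Ier2 (-0.28) fell and none rose; adjusted over the list alone, 4 fell (camera adjusted p = 0.0725). Without control 1 or 2, 2 NRF2 targets fell and without control 3, 1; Gsta2 was lost without any control or POMCMfn2KO 1, 2 or 3 (adjusted p up to 0.132), Gpx4 without any control (0.0837) and Nqo1 without control 3 (0.0542). The NRF2 list passed camera without POMCMfn2KO 5 (adjusted p = 0.0351). Without control 1 or 3, 2 glucocorticoid-responsive genes rose, and without any control 1 fell. The immediate early list passed camera without POMCMfn2KO 1 (adjusted p = 0.0272, 6 fell) or 5 (0.0499), and 1 of its genes fell without control 1 or 3 and 1 rose without POMCMfn2KO 4.

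Clock genes moved in opposite directions in POMCMfn2KO liver. Cry1, a repressor, rose from 7.16 ± 0.03 to 8.77 ± 0.31 (3.05-fold), and Arntl, the gene of the activator BMAL1, rose from 8.24 ± 0.00 to 8.92 ± 0.14 (1.60-fold). Dbp, an output factor driven by BMAL1, fell from 10.07 ± 0.06 to 7.90 ± 0.21 (4.49-fold), and its relative Tef fell from 10.41 ± 0.06 to 9.70 ± 0.06 (1.64-fold). Dimmer probe sets gave 0.13 for Arntl and -0.06 for Tef. Of 19 clock genes, 4 rose and 9 fell; adjusted over the list alone, 5 rose and 10 fell (camera adjusted p = 0.0954). The number that fell was 5 without control 1 or POMCMfn2KO 3, 4 without control 3, and 4 without POMCMfn2KO 2 and 3. Collection times are not in the labels, and whether they contribute to the changes of other genes described here was not tested.

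**Figure D2:**
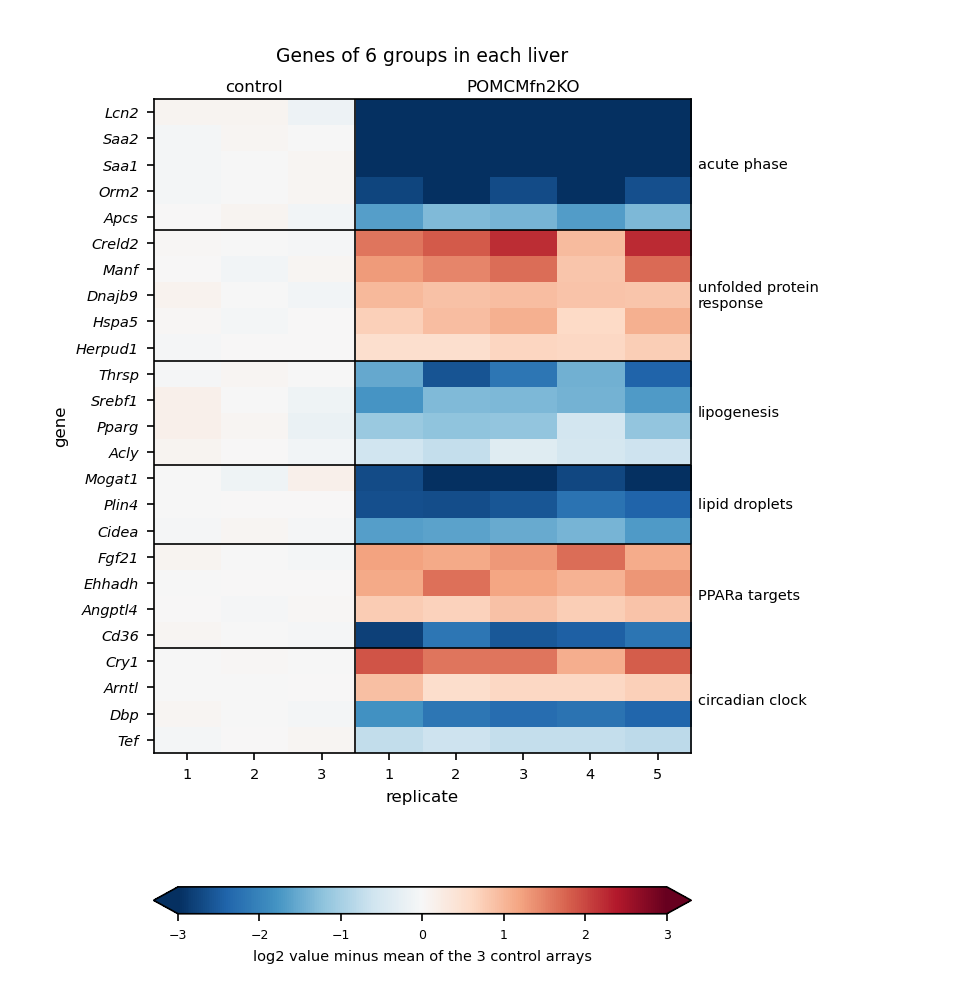
Log2 level of genes from 6 groups in each of the 8 livers, minus the mean of the 3 controls; colours saturate at 3 in either direction. The acute phase, lipogenesis and lipid droplet genes drawn here, chosen from those past the gene test, fell, the unfolded protein response genes drawn rose, and Cry1 and Arntl moved opposite to Dbp and Tef.

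Several genes with male-biased liver expression rose. Egfr rose from 9.78 ± 0.03 to 11.86 ± 0.30 (4.24-fold), the glucuronosyltransferase gene Ugt2b38 rose from 7.70 ± 0.21 to 10.91 ± 0.88 (9.27-fold), and Slco1a1 and the complement gene C8b (1.08) also rose. Of 14 male-biased genes, 7 rose and none fell; adjusted over the list alone, 10 rose and 1 fell. Camera gave adjusted p = 4.63e-05, and adjusted p = 0.406 with an estimated correlation. Of 13 female-biased genes, Cyp17a1 (1.63) and Nipal1 (1.34) rose and Atp6v0d2 (-0.71) and Rtn4 (-0.68) fell, over all genes and adjusted over the list alone (camera adjusted p = 0.760). The 3 tested sex chromosome genes, Eif2s3y (0.01), Kdm5d (0.05) and Uty (-0.00), did not pass (0 at an unadjusted p under 0.05 in limma, and 0 adjusted over the list alone). Their mean was 7.99 ± 0.05 in controls and 8.01 ± 0.13 in POMCMfn2KO. Xist was dim and not tested, at 5.32 ± 0.10 in controls and 5.38 ± 0.09 in POMCMfn2KO. These values argue against a difference in sex between the groups as the source of the rise of male-biased genes. Without control 2 or 3, 4 male-biased genes rose, and without POMCMfn2KO 1, 11; 1 fell without POMCMfn2KO 3 or 4. No female-biased gene rose without any control, and 1 rose without POMCMfn2KO 2 or 3. Nipal1 (adjusted p up to 0.0606) and Cyp17a1 (up to 0.0964) were lost without any single control, Cyp17a1 also without POMCMfn2KO 2 or 3, Atp6v0d2 lay below the level used to leave out dim genes in POMCMfn2KO (5.73 ± 0.20), and other probe sets of Rtn4 included values of 0.07 and -0.09.

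Xenobiotic metabolism was mixed. The carboxylesterase gene Ces2a (0.66) and the glucuronosyltransferase gene Ugt2b1 (0.58) rose, while Aldh1a7 (-1.30) and the glutathione transferase gene Gstt1 (-0.77) fell. Of 25 genes, 4 rose and 7 fell; adjusted over the list alone, 4 rose and 8 fell (camera adjusted p = 0.137). Of 21 urea cycle and amino acid genes, Cps1 (0.31) and Cbs (0.27) rose and Glul (-0.48) fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.712). Without any control, 2 xenobiotic genes rose and 2 fell; 2 rose without POMCMfn2KO 2, 3 or 5, and 3 fell without POMCMfn2KO 3. No urea cycle or amino acid gene rose without any control or POMCMfn2KO 3, 1 rose without POMCMfn2KO 2, and 2 fell without POMCMfn2KO 1 or 4.

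Oxidative phosphorylation genes lay slightly higher as a list with no single gene past the test. Of 33 members 0 passed in limma, 0 adjusted over the list alone and 6 at an unadjusted p under 0.05; the lowest p were those of Ndufs7 (0.36), Cycs (0.34), Uqcrc1 (0.18) and Cyc1 (0.19). Camera gave adjusted p = 0.0340, and adjusted p = 0.683 with an estimated correlation. Of 19 genes of mitochondrial dynamics, 0 passed in limma (3 at an unadjusted p under 0.05), 0 adjusted over the list alone (camera adjusted p = 0.569). Mfn2 itself stood at 9.88 ± 0.08 in controls and 9.61 ± 0.24 in POMCMfn2KO (-0.27, adjusted p = 0.169); its deletion was in neurons. Of the 4 tested genes of the melanocortin axis with Mfn2, 0 passed in limma (0 at an unadjusted p under 0.05), 0 adjusted over the list alone, and Pomc differed by -0.05. The oxidative phosphorylation call was lost without control 1 or 3 or POMCMfn2KO 1, 3 or 4 (adjusted p up to 0.146) and with array weights (0.0767); 1 member passed without POMCMfn2KO 1 or 5 and 2 without POMCMfn2KO 4. In mitochondrial dynamics 1 gene rose and 3 fell without POMCMfn2KO 1, 2 rose without POMCMfn2KO 4, and 1 gene of the melanocortin axis list fell without POMCMfn2KO 1.

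Among hepatocyte identity genes, no gene of the secreted protein list passed, while Cps1 and Asgr1 passed among the hepatocyte markers. Of 18 secreted proteins 0 passed in limma (2 at an unadjusted p under 0.05), 0 adjusted over the list alone (camera adjusted p = 0.683), with Alb at 15.26 ± 0.02 and 15.25 ± 0.01. Of 11 hepatocyte markers, Cps1 rose and Asgr1 (-0.33) fell; adjusted over the list alone, 1 rose and 2 fell (camera adjusted p = 0.712). Of 16 proliferation genes, Mcm2 (-0.69) fell, also adjusted over the list alone (camera adjusted p = 0.462), and of 8 fetal and young liver genes 0 passed in limma (3 at an unadjusted p under 0.05), 0 adjusted over the list alone (camera adjusted p = 0.669). Cps1 was lost without any control or POMCMfn2KO 3 and Asgr1 without control 2 or 3, leaving 0; 4 proliferation genes fell without POMCMfn2KO 5 and 1 rose without POMCMfn2KO 4. Without POMCMfn2KO 1, 2 hepatocyte markers rose and 2 fell, and 1 fetal gene rose and 1 fell; without POMCMfn2KO 4, 2 hepatocyte markers and 1 fetal gene rose.

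Several markers of immune cells fell in POMCMfn2KO liver and several endothelial markers rose. The Kupffer cell and macrophage markers Mpeg1 (-0.74), Timd4 (-0.69) and Folr2 (-0.50) fell, Cd5l did not pass (-0.57, adjusted p = 0.0512), and Ighm, the immunoglobulin M heavy chain gene, fell from 9.35 ± 0.40 to 7.47 ± 0.25 (3.66-fold) with Jchain (-1.36) and Blnk (-0.61). Other probe sets above the filter gave -1.63, -0.04, -0.09 and -0.06 for Ighm and 0.11 to 0.21 for Fcgr2b, and Jchain (5.79 ± 0.37) lay below the level used to leave out dim genes in POMCMfn2KO. Among the controls, 20 of the 23 Kupffer cell, macrophage, B cell and plasma cell markers were highest in control 1, with a median SD of 0.1597 over the 3 controls. The sinusoidal endothelial markers Bmp2 (0.55), Stab2 (0.55), Fcgr2b (0.41) and Eng (0.24) rose. Of 15 Kupffer cell and macrophage markers 3 fell, and 5 adjusted over the list alone (camera adjusted p = 0.0110; adjusted p = 0.683 with an estimated correlation). Of 8 B cell and plasma cell markers 3 fell, and 3 adjusted over the list alone, with H2-Ab1 not passing at -0.22 (camera adjusted p = 0.0443; adjusted p = 0.406 with an estimated correlation). Of 15 endothelial markers 4 rose, and 7 adjusted over the list alone (camera adjusted p = 0.00115; adjusted p = 0.509 with an estimated correlation). The Kupffer call was lost without control 1 or POMCMfn2KO 4 (adjusted p up to 0.0658), with 7 markers falling without POMCMfn2KO 5, and the B cell call without control 1 or POMCMfn2KO 2, 3, 4 or 5 (up to 0.0657), with 5 falling without POMCMfn2KO 1. The B cell call was also lost with replicate numbers as a block (0.0864), with the mean of all probe sets (0.0840) and without POMCMfn2KO 2 and 3 together (0.0720). Endothelial markers that rose numbered 1 without control 2, 0 without control 3, 2 without POMCMfn2KO 2, 3 or 5, and 1 without POMCMfn2KO 2 and 3 together. Among these genes, Folr2 (adjusted p up to 0.192) and Eng (up to 0.157) were lost without any control and Fcgr2b (up to 0.162) and Stab2 (up to 0.0569) without control 2 or 3, Bmp2 without control 3 (0.0541), and the first 3 also without POMCMfn2KO 2 or 3; Folr2 was lost without POMCMfn2KO 4, Eng and Fcgr2b without POMCMfn2KO 5 and Eng without POMCMfn2KO 1, and another probe set of Eng gave -0.09. With replicate numbers as a block Folr2 (0.107), Fcgr2b (0.149) and Eng (0.0595) were lost, and with the mean of all probe sets Fcgr2b (0.129) and Eng (0.513).

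Pancreatic digestive enzyme transcripts were abundant in POMCMfn2KO 2 and 3 and near the control level in the other livers, apart from Cela1 at 10.16 in POMCMfn2KO 4. The mean of the 11 tested acinar markers was 10.46 and 10.65 in these livers and 6.33 to 6.60 in the other 6; the carboxypeptidase gene Cpb1 reached 11.69 and 11.68 there, against 4.79 ± 0.28 in controls, and Cela2a (2.54), Clps (1.75) and Cela1 (1.45) followed the same livers. No acinar marker passed in limma (0 at an unadjusted p under 0.05), 0 adjusted over the list alone; camera gave adjusted p = 0.0269, and adjusted p = 0.683 with an estimated correlation. Skeletal muscle markers were also highest in these livers, with a mean of 7.45 and 7.61 against 6.38 to 6.95 elsewhere: Acta1 (1.32), Tnnc2 (0.82), Mylpf (0.61) and Tnni2 (0.60). In controls Cpb1, Clps and Tnni2 lay below the level used to leave out dim genes, so background limits the size of their differences. Of 8 muscle markers 0 passed in limma (4 at an unadjusted p under 0.05), 0 adjusted over the list alone (camera adjusted p = 0.0340; adjusted p = 0.683 with an estimated correlation). The acinar call was lost without control 1 or POMCMfn2KO 2 or 3 (adjusted p up to 0.0650), and the muscle call without control 1 or 3 or POMCMfn2KO 2, 3 or 4 (up to 0.0797) and with the mean of all probe sets (0.0934), while 4 muscle markers passed without POMCMfn2KO 1. Without POMCMfn2KO 2 and 3, the acinar list gave adjusted p = 0.244 and the muscle list 0.130. In that fit 4 lipogenesis genes fell and 0 rose, 11 acute phase genes fell, 5 male-biased genes rose, 2 bile acid genes rose, 2 Kupffer cell and macrophage markers, 2 interferon response genes and 2 NRF2 targets fell, 2 xenobiotic genes rose and 1 fell, and 1 glucocorticoid-responsive gene rose and 1 fell; 24 of the 87 named genes past the test lost their calls: Ccn2, Mt1, Mt2, Nat8, Igfbp1 and Pck1 as given above, Serpina7 (adjusted p = 0.0637), Gyg (0.0774), Ugp2 (0.1005), Gbe1 (0.1004), Abcb4 (0.0970), Cyp7b1 (0.107), Gpx4 (0.105), Gsta2 (0.155), Oasl1 (0.0526), Ifit1 (0.0543), Gstt1 (0.0628), Nipal1 (0.0674), Cyp17a1 (0.114), Folr2 (0.116), Stab2 (0.0751), Fcgr2b (0.1598), Eng (0.176) and Ddit3 (0.0545). List medians went from -0.54 to -0.62 for the acute phase, -0.31 to -0.32 for xenobiotic metabolism, 0.10 to 0.14 for glucocorticoid-responsive genes, 0.72 to 0.64 for male-biased genes, -0.33 to -0.40 for the interferon response, -0.32 to -0.30 for Kupffer cells and -0.17 to -0.13 for lipogenesis, while the bile acid median went from -0.02 to 0.03. Other medians went from -0.20 to -0.12 for glycogen metabolism, -0.12 to -0.30 for cholesterol synthesis, -0.29 to -0.19 for immediate early genes, 0.60 to 0.26 for skeletal muscle and 1.76 to 0.06 for acinar markers.

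**Figure D3:**
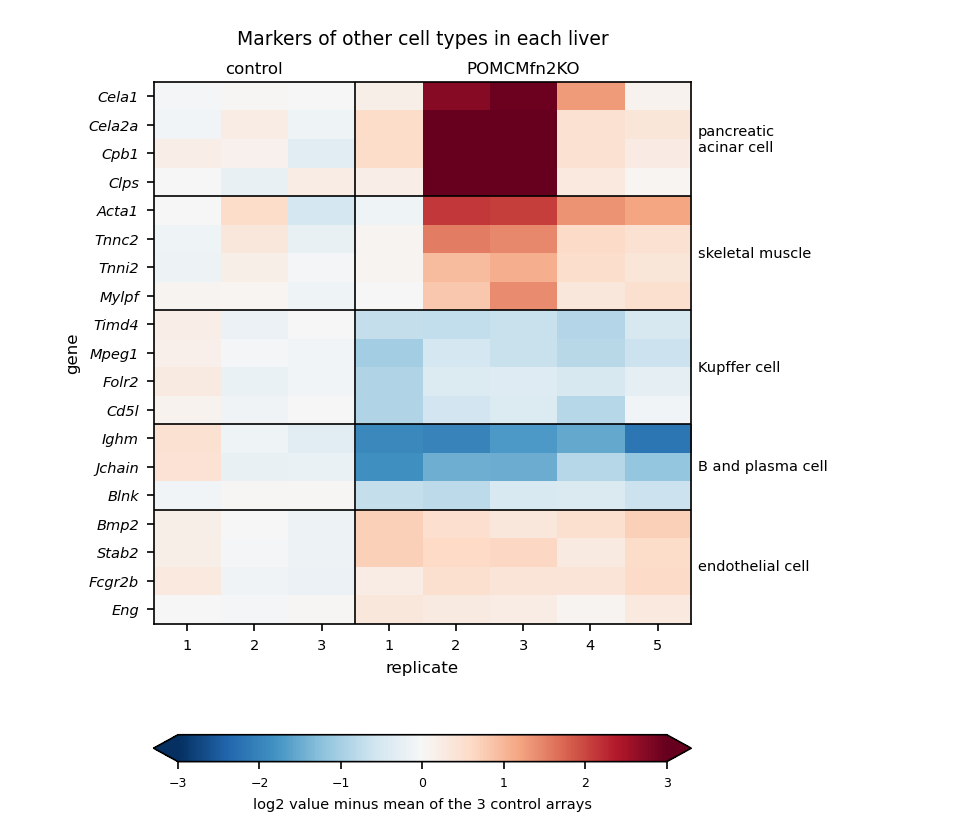
Log2 level of markers of other cell types in each of the 8 livers, minus the mean of the 3 controls; colours saturate at 3 in either direction. Acinar transcripts are high in POMCMfn2KO 2 and 3 alone except for Cela1, which is also raised in POMCMfn2KO 4, and Ighm is lower in all 5 POMCMfn2KO livers.

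Other cell types showed few changes. Of 8 neutrophil markers, S100a9 (-1.56) and Lcn2 fell, 2 also adjusted over the list alone (camera adjusted p = 0.0518), and the list passed camera without control 2 (0.0434) or POMCMfn2KO 1 (0.0453) or 2 (0.0352). Of 15 stellate cell and fibroblast markers, Hand2 (0.40) rose, 0 adjusted over the list alone (camera adjusted p = 0.285). Of 7 erythroid markers, Tfrc (0.86) rose and Car1 (-0.82) fell, also adjusted over the list alone (camera adjusted p = 0.544). Of 5 adipocyte markers, Fabp4 (0.48) rose; adjusted over the list alone, 1 rose and 1 fell (camera adjusted p = 0.795). None of 6 cholangiocyte markers (1 at an unadjusted p under 0.05 in limma; camera adjusted p = 0.737) or 5 T and NK cell markers (1; camera adjusted p = 0.462) passed, 0 adjusted over the list alone. Without control 2 or 3, 0 of Hand2, Tfrc, Car1 and Fabp4 passed; Tfrc and Car1 were also lost without control 1 or POMCMfn2KO 2 or 5, Car1 without POMCMfn2KO 1 or 3 and Hand2 without POMCMfn2KO 2, 4 or 5. Without POMCMfn2KO 5, 1 cholangiocyte marker rose and 1 T and NK cell and 1 stellate marker fell, and 1 adipocyte marker fell without POMCMfn2KO 1 or 4.

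Over all 39 lists tested, 12 passed camera, 7 up and 5 down. With an estimated correlation 0 passed in limma, with 2 lists at an unadjusted p under 0.05. By fry 13 lists passed, 6 of them among the 12. Of the 12, the interferon response (adjusted p = 0.271), oxidative phosphorylation (0.277), Kupffer cell (0.161), endothelial (0.0700), acinar (0.349) and muscle (0.271) lists did not pass fry. The 7 lists that passed fry but not camera were neutrophil markers (fry adjusted p = 0.000183), lipid droplets and lipoproteins (0.000265), circadian clock (0.00263), insulin signalling (0.00715), glycogen metabolism (0.00785), immediate early genes (0.0173) and glycolysis (0.0402). The neutrophil list had a mean change of -0.89 but a median of -0.11. Only 2 of its 8 markers, Lcn2 and S100a9, fell, and Lcn2 is also an acute phase gene, so the result does not show fewer neutrophils. The exact permutation test of the list means gave p under 0.05 in 13 lists, and in 0 after adjustment. Without control 1, 5 lists passed camera, and without POMCMfn2KO 3 or 4, 7.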

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

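The comparison of list counts over splits, the test on spike-ins and the test of a shared control extract were chosen only after the result was seen; the count of genes over splits and the test on other probe sets were set out before.

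In 6 of the 135 genes and list means examined in the 5 POMCMfn2KO livers, 1 liver lay far from the others, with its gap to the nearest liver above 0.71 of the whole range; chance alone gives that in about 1 in 20. POMCMfn2KO 4 stood apart for Igfbp2 (0.766), Nat8 (0.831), Pparg (0.836) and Gstt1 (0.766). POMCMfn2KO 1 stood apart for Ndufs7 (0.743) and for the mean of the interferon response (0.737). Outside the named genes, 379 of 2855 bright probe sets with no single gene symbol passed the limma test, 219 higher and 160 lower.

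The pattern weighed here is the extent of the change, 2152 genes, beside control livers that differed little from each other. The median SD was 0.0686 in controls and 0.135 in POMCMfn2KO, and 1 to 2 genes differed by over 2-fold between any 2 controls against 25 to 241 between POMCMfn2KO livers. Only 1 of the 56 splits of the 8 arrays, the real one, gave as many genes, with 781 as the highest of the others. That makes a random grouping of the arrays unlikely, but 1 of 56 is the smallest share possible (0.0179), so chance is not excluded. The controls also varied less than POMCMfn2KO, so any cause that sets 3 alike arrays apart could rank first as well. The split with 781 genes set POMCMfn2KO 2, 3 and 5 apart, which points to a structure among the livers. Of 958 called genes with another bright probe set, 88.6% moved in the same direction there, with a median ratio of the changes of 0.70. Where the names of both probe sets marked no sharing between transcripts (427 genes), the share was 84.5%. These shares argue against a hybridisation difference of single probe sets. Immune cell markers varied more among the controls (median SD 0.1597) than in any random gene list (highest 0.109). The random lists ignored that such markers vary together, so they do not measure how unusual this is. The larger spread goes against 1 RNA extract on all 3 arrays, but does not exclude it. Since 20 of the 23 markers were highest in control 1, a shared extract of controls 2 and 3 stays open. The bacterial hybridisation spike-ins, added to every sample, were 0.21 higher in POMCMfn2KO (exact permutation p = 0.0179, 14 of 18 probe sets without overlap), so handling or array batch may differ between the groups and cannot be told apart from genotype, which stays untested as the biological explanation, because the labels give no batch.

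For the gene lists, 5 of the 56 splits gave as many lists past camera as the real split (12, with 16 as the highest of the others), so chance cannot be excluded for the number of lists.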

How the results depend on the processing

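Array weights by genotype, averaged controls and leaving out POMCMfn2KO 2 and 3 together were chosen after seeing the data. The number of called genes was within 1.5 times of 2152 under 11 alternatives, from 1880 (mean of all probe sets) to 3216 (adjusted p under 0.10), among them 3210 with weights by genotype. It was higher with every probe set tested (3452; more features tested) and with array weights (4394; the cause was not tested). It was lower in an ordinary test without moderation (1418) and with an unadjusted p under 0.01 and a change of at least 1.5-fold (577, a stricter threshold on size). With the controls averaged it was 31, and without POMCMfn2KO 2 and 3 it was 640. The cause of the lower counts of 1418, 31 and 640 was not tested. The last 2 fits held fewer samples, yet the count also depended on which array was removed. It ran from 820 to 2760 when 1 array was left out, with 1399 without POMCMfn2KO 3 and 2760 without POMCMfn2KO 1. The number of lists past camera was 0 with an estimated correlation (the cause was not tested), 5 to 13 when 1 array was left out, and 8 to 16 otherwise. With replicate numbers as a block, 1891 genes (1525 of the 2152) and 13 lists passed, and the gluconeogenic mean differed by 0.14. The residuals of arrays with the same number correlated at 0.04, 0.04 and -0.03, against -0.08 to 0.05 for unlike numbers. These values show no pairing of the mice by number, but they are too few to exclude it. The gluconeogenic mean difference stayed positive under each alternative, at 0.03 to 0.12 when 1 array was left out. No exact permutation test of it passed, though 3 arrays against 3 could not have passed (smallest possible p 0.1), and the block value was not tested. Of 87 named genes past the test, 59 passed in every setting run on them. Genes that did not pass reversed as follows, and the cause was not tested: H2-Ab1 0.016 (mean of all probe sets), Pcx 0.057 (block), Ppargc1a 0.30 (block) and -0.37 to 0.19 when 1 array was left out, and Fasn -0.14 to 0.013 when 1 array was left out and 0.029 without POMCMfn2KO 2 and 3. A fit with Xist as a covariate was not run, since Xist was low in all 8 arrays. With each array centred on its median, 1055 genes rose and 1119 fell (48.5% higher, against 39.1%). Signal near background limits the 6207 dim genes, which were not tested, and the size of the falls of Serpina7, Mogat1, Cidea, Jchain, Atp6v0d2, Ciart, Per3 and Nr1d1. It also limits the size of the differences of Cpb1, Clps and Tnni2.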

Other observations

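All tests in this part were chosen only after the result was seen.

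Several heat shock proteins and cochaperones rose in POMCMfn2KO liver. Hspa1b, an inducible HSP70 gene, rose by 2.18, Hsph1 by 1.72, Chordc1 by 1.20, Hspa8 by 0.73 and Dnajb1, an HSP40 gene, by 0.68. Of 18 tested members of this list, put together after the values were seen, 12 rose, 0 fell and the others did not pass; 7 rose without POMCMfn2KO 2 and 3. Its mean differed by 0.60, but the list was chosen from these values, so the exact permutation p of 0.0179 is no evidence for the group.

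Called genes lay beside each other on the chromosomes more often than in random orders: 279 adjacent pairs changed in the same direction, against a median of 202 and a highest value of 246 in 10000 permutations (permutation p = 1e-04, the smallest they can give). The permutations moved the calls freely over all placed genes, without regard to mean level or to related neighbours. Probe sets of close relatives can bind each other's transcripts, so the excess of pairs does not show that neighbours are regulated together.

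The opposite movement of clock genes is a pattern with a candidate technical source, tissue collected at another clock time in each group. All 4 tested genes in phase with Arntl rose (Arntl, Clock, Cry1 and Nfil3), and 7 of 11 in phase with Dbp fell while none rose, so all 11 called genes of these arms moved with their arm; without POMCMfn2KO 2 and 3, 3 of the Dbp arm fell. Wee1 and Cry2, which also fell, were placed in neither arm. The values fit a shift in clock time, yet the labels give no collection time, and a shift of the liver clock in the mutant would look alike. The hours of collection and a change of the clock cannot be told apart. Whether either also moved genes outside the clock, such as the gluconeogenic, lipogenic or heat shock genes above, was not tested.

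Pancreatic transcripts in POMCMfn2KO 2 and 3 are the other pattern weighed. All 11 bright acinar markers exceeded the highest control by over 1 in both livers, which is consistent with pancreatic tissue in the collected piece as a hypothesis; no biological explanation was tested. Since acinar cells express chaperones of the endoplasmic reticulum at high levels, their RNA might account for the rise of the unfolded protein response. Without these livers the median change of its 12 risen genes was 0.72 instead of 0.82, 88.4% of its value, and all 12 lay above every control in the 3 livers left. The 12 were chosen by a test that included those 3 livers, so this outcome was largely set in advance and is no support by itself. Over all 24 tested members, listed before the values were seen, the median was 0.36 without these livers instead of 0.37. That argues against pancreatic RNA as the whole cause. Of the 12, 6 still passed with fewer arrays, and the list mean gave an exact permutation p of 0.1 over 20 splits, the smallest possible there; genotype and collection time stay open.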
